A study of Mus musculus with 6 samples.

How the data were processed

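RNA-seq libraries were made from mouse trigeminal ganglia of male C57BL/6J mice, 3 control and 3 diabetic. Per the labels' protocols, streptozotocin at 90 mg/kg, or citrate buffer, was injected into the peritoneum on 2 consecutive days at 7 weeks of age. Mice with blood glucose above 15 mmol/L at 5 days after the last injection were taken as diabetic, and tissue was analysed 4 months after induction. Per the labels' protocols, RNA was enriched with a poly(A) module and libraries were built with a stranded kit; the same text also mentions rRNA depletion as an option, so the selection is not fully settled. The submitters' processing notes name the builds GRCm38 and mm10, and the aligner and the tool that estimated expression are not given in the sources used here.

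Both tables hold FPKM per library, deposited by the authors as a gene table and a transcript table per the file headers, with 1 column per library; each column was matched to a sample by its title. FPKM scales each value to the length of the feature and to the library's total, so a change in a few abundant transcripts shifts all others. The tables hold no read counts. Low values were searched for whole-read steps, and the highest coherence (0.147 to 0.182) lay under that of jittered values in every library, so depth is unknown and no interval that needs it is given. Every gene and transcript listed has a mean of at least 0.5 FPKM in the larger group (smallest 0.501 for genes), so the tables appear to have been filtered on group means. The labels do not say whether counting used strand, so values of antisense, intronic and overlapping lncRNA genes may include reads of the gene they overlap. Values of isoforms are estimates that divide shared reads. Gene coordinates follow the deposited tables. Of 15146 gene identifiers, 15107 are in GENCODE release M21 on GRCm38, 13933 with identical coordinates. GC content of the transcripts was computed from that release for 15126 genes. A gene was given the GC content of its listed transcript with the highest mean FPKM over the 6 libraries.

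Tests used log2(FPKM + 0.1) for genes with a mean of at least 0.5 FPKM over the 6 libraries, which left out 277 genes and 3296 transcripts. limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) compared diabetic with control libraries with no block, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A fold change on the log2(FPKM + 0.1) scale understates the change of low genes. lncRNA genes are those whose type in the table is a lncRNA type. Fixed gene lists (43, of which 38 had at least 5 tested members) covered neuron types, glia, immune cells, metabolic and stress processes, and other tissues that a dissection can carry along. They were tested with camera at its preset correlation of 0.01, beside camera with an estimated correlation, fry and member counts. lncRNA neighbours were taken from the tables' coordinates, with 1000 draws from 10 expression bins. Values per library were compared with exact permutation tests, two-sided, for which 0.1 is the smallest p that 3 against 3 allows. Other statistics used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6, and plots matplotlib 3.10.9.

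The test, the lists, the threshold, the alternatives and the rule for the genes named were fixed before the data were examined. The rule takes, among genes past the threshold with non-overlapping groups, the 10 largest rises and falls (5 for lncRNA genes). Where fewer than 5 pass in a direction (2 for lncRNA genes), it takes those with the smallest unadjusted p, up to 5 (3 for lncRNA genes). For each list described it takes up to 4 members that pass, or, where fewer than 2 pass, the 2 with the smallest p. It always takes Calca, Tac1, Trpv1, Trpm8, Mrgprd, Atf3, Fabp7, Malat1, Neat1 and Meg3, and 1 more gene that is not reported here, and for transcripts the 5 largest rises and falls past the threshold. Gh, Prl, Pomc and Ccm2-201 were named after their values were seen. Which lists are described by their members (26 of 43) was also chosen after the values were seen; 5 lists had too few tested members for camera.

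Alternatives planned were each replicate left out, the replicate number as a block, a pseudocount of 1 or 0.01, no filter or a mean of at least 1 FPKM, trimmed-mean and quantile scaling, other variance models, looser thresholds, other list tests, and distances of 50 and 500 kb. A GC correction was added after the data were seen: in each library a loess curve (span 0.3) of the deviation from the gene mean on GC content was subtracted. Sets without the libraries in doubt were added in the same way.

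The test was checked on simulated values drawn around the means and residual SDs of 14850 genes, with 200 genes changed. Without a GC trend, 19.4% of 1.5-fold, 68.7% of 2-fold and 93.9% of 4-fold changes passed, with 11 false calls. With a GC trend added to 2 libraries and left in, since the main test makes no GC correction, 11.9%, 67.2% and 93.9% passed, with 6 false calls. The added trend was weaker than that of the data, with Spearman's rho of fold change with GC content at 0.50 against 0.69. With the trend added and then removed by the correction, 11.9%, 68.7% and 89.4% passed, with 9 false calls. Apart from the added trend, genes were drawn independently, so these rates need not hold for the data. The list and neighbour tests recovered the changes put into simulated values of independent genes, and lists whose members vary together were not simulated.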

Results

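Trigeminal ganglia, which hold the cell bodies of the sensory neurons that supply the cornea, were compared between mice made diabetic with streptozotocin, a toxin of pancreatic beta cells, and mice given citrate buffer. The series asks which long non-coding RNAs (lncRNAs) differ in the ganglion in diabetic corneal neuropathy. There were 3 control and 3 diabetic RNA-seq libraries. The labels do not state whether each library came from 1 animal or from a pool, so p-values measure the spread between these samples. The gene table held 15146 genes (13881 protein-coding and 1265 lncRNA genes) and 46721 transcripts were listed in the transcript table, all as FPKM. Summed gene FPKM lay between 186062 and 195263 per library. Read totals were not in the tables and could not be recovered from the low values, so the depth behind each value is unknown. Values below are means ± SD over the 3 libraries of a group, and fold changes are diabetic against control on the log2(FPKM + 0.1) scale with their SE.

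The first comparison asked which genes differed between diabetic and control ganglia. Among the genes with the smallest unadjusted p, Pigc, a subunit of the enzyme that starts GPI anchor synthesis, was at 3.17 ± 0.426 FPKM in controls and 1.12 ± 0.179 in diabetic mice (log2 fold change -1.42 ± 0.19), and Rcbtb1 was at 11.4 ± 1.09 and 5.85 ± 0.585 (-0.95 ± 0.13). Slc25a22, a mitochondrial glutamate carrier, had a log2 fold change of -0.79 ± 0.14, Crls1, the cardiolipin synthase of mitochondria, -0.58 ± 0.11, and Tollip, an adaptor of Toll-like receptor signalling, -0.58 ± 0.12. The gene and isoform values of Slc25a22 disagree, as given below with its isoform. On the other side, Dact3, an antagonist of Wnt signalling, was at 9.82 ± 0.229 FPKM in controls and 19.7 ± 3.92 in diabetic mice (0.97 ± 0.16). Rgs6, a regulator of G protein signalling, had a log2 fold change of 0.99 ± 0.16. The postsynaptic proteins Prr7 and Dlgap3 had 0.93 ± 0.16 and 0.68 ± 0.12, and the presynaptic adhesion molecule Nrxn2 0.57 ± 0.10.

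For each of these 10 genes all diabetic values lay on one side of all control values, but none passed the threshold. With limma and Benjamini-Hochberg adjustment, 0 of 14869 genes tested had an adjusted p under 0.05, and the smallest was 0.52. At an unadjusted p under 0.05 there were 1320 genes, 621 higher and 699 lower, where chance alone gives 743.45. Other splits of the 6 libraries 3 against 3, which mix the groups, gave 106 to 1547 such genes. An excess over 743.45 thus also arises between sets that mix the groups. Of the 1320 genes, 374 differed by at least 1.5-fold, 163 higher and 211 lower. This balance turned without control replicate 2 (189 higher and 98 lower), without diabetic replicate 2 (294 and 126) and without diabetic replicate 3 (92 and 76). It was 434 and 948 without diabetic replicate 1, and 70 and 56 after a correction for GC content that was added after the data were seen. Groups did not overlap for 2465 genes (16.6%), where chance gives 10%, and this share was not counted for other splits. Without diabetic replicate 1 there were 314 genes past the threshold, 176 higher and 138 lower, and without control replicate 3 there were 2, Tomm5 (1.97 ± 0.14) and Smco3 (-2.33 ± 0.16), which are named here after their values were seen. In GENCODE coordinates of GRCm38, Pigc lies on chromosome 1 at 161969186 to 161973435, Rcbtb1 on chromosome 14 at 59201209 to 59237265, Rgs6 on chromosome 12 at 82588292 to 83162056, and Dact3 on chromosome 7 at 16875317 to 16887462.

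**Figure D1:**
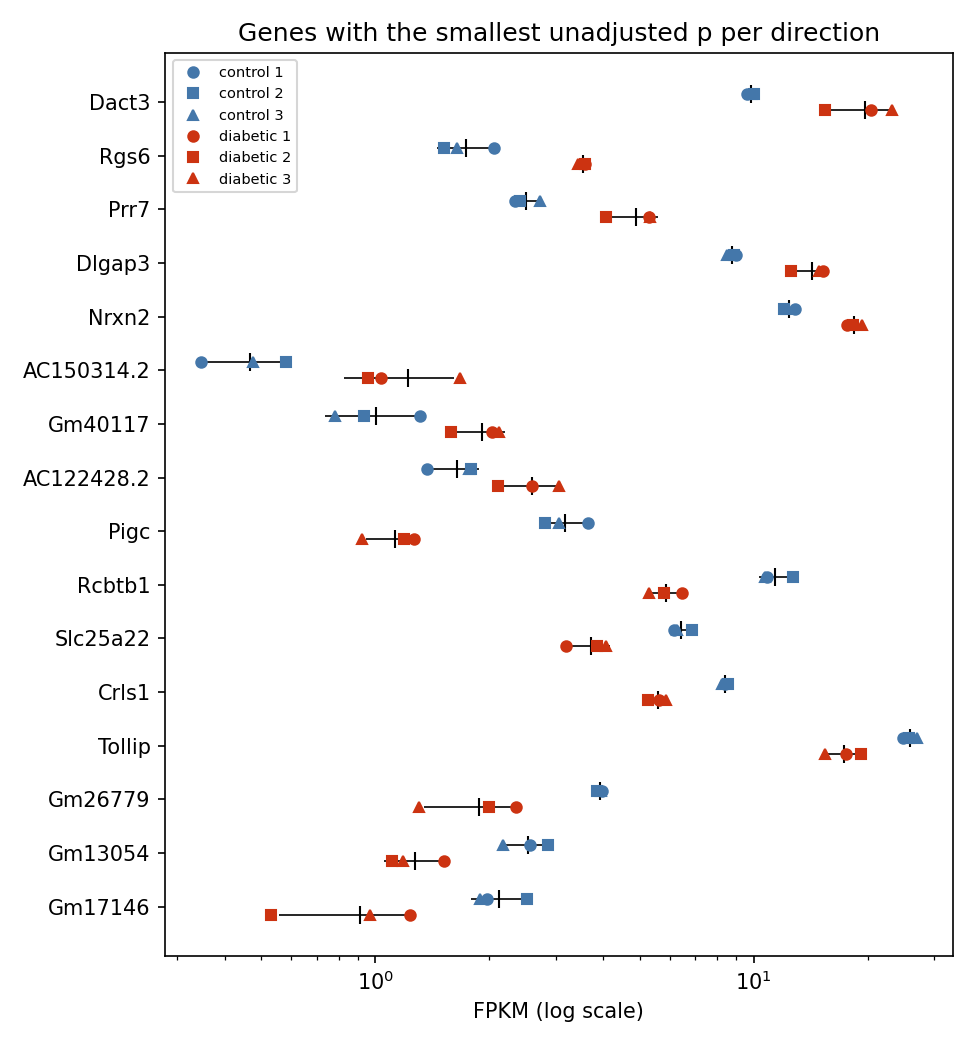
FPKM on a log axis, per library, of the genes and lncRNA genes with the smallest unadjusted p in each direction; points are libraries, and black ticks with bars are the group mean ± SD. The 3 diabetic values of Pigc and Rcbtb1 lie below, and those of Dact3 and Rgs6 above, all 3 control values, while the adjusted p of each gene shown is 0.52.

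The fold changes of genes followed the GC content of their transcripts. With the genes ranked by GC content and cut into 5 equal groups, the median log2 fold change was -0.30 in the group with the least GC (25.6% to 44.5%) and 0.24 in that with the most (56.2% to 76.3%). Of the genes with an unadjusted p under 0.05, the GC-poorest group held 530 lower and 3 higher genes and the GC-richest 7 lower and 418 higher. Spearman's rho of fold change with GC content was 0.69 across 14850 genes, which are not independent replicates. The slope of a gene's deviation from its mean on GC content, per 10 percentage points, was -0.18, -0.15 and -0.14 in the controls and -0.07, 0.15 and 0.40 in diabetic replicates 1, 2 and 3. Among the named genes, Prr7 (69.0% GC), Dact3 (66.4%), Dlgap3 (64.7%) and Nrxn2 (64.0%) were GC-rich and higher. Pigc (45.4%), Crls1 (46.3%), Rcbtb1 (47.5%) and Rgs6 (48.0%) were not GC-rich. Slc25a22 was lower, and its value of 60.6% is that of its retained-intron isoform Slc25a22-212. That isoform held 1.56% of the gene's summed isoform FPKM in controls and 50.4% in diabetic libraries. The GC value of Slc25a22, and its correction, thus rest on an isoform nearly absent from controls. After the GC correction the log2 fold changes were 0.43 for Prr7, 0.53 for Dact3, 0.29 for Dlgap3 and 0.19 for Nrxn2, and they were -1.25 for Pigc, -0.44 for Crls1, -0.85 for Rcbtb1 and 1.08 for Rgs6. That of Slc25a22 was -1.07, larger in size than the -0.79 before it, with the smallest unadjusted p after the correction (9.6e-06, adjusted p = 0.143). Of the 77 genes that the naming rule takes, 38 had a fold change over 1.5 times smaller in size after it. Among those described below were Cdh19 (-0.54 before and -0.07 after), Etv1 (-0.44 and -0.18) and Asic2 (0.31 and 0.05).

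**Figure D2:**
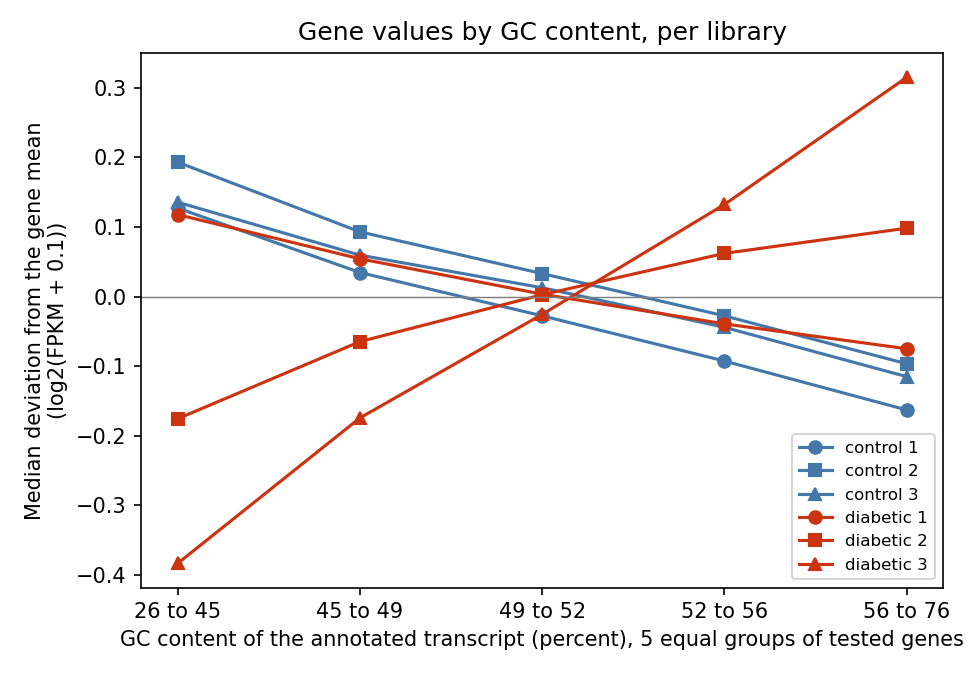
Median deviation of a gene from its mean over the 6 libraries (log2 scale, vertical axis) in 5 equal groups of tested genes by GC content in percent (horizontal axis), 1 line per library. The 3 controls and diabetic replicate 1 slope downward, and diabetic replicates 2 and 3 slope upward, from -0.18 to 0.10 and from -0.38 to 0.32.

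The second comparison concerned lncRNA genes. The lowest unadjusted p belonged to Gm26779, a lincRNA gene on chromosome 5 at 109886231 to 109891137, at 3.92 ± 0.0626 FPKM in controls and 1.88 ± 0.536 in diabetic mice (log2 fold change -1.06 ± 0.22), Gm13054 (-0.95 ± 0.20), an antisense gene on chromosome 4 at 148001091 to 148004014, and Gm17146 (-1.19 ± 0.30). On the higher side were AC150314.2 (1.20 ± 0.31), which shares a promoter region with a coding gene by its type, the antisense gene Gm40117 (0.88 ± 0.24) and the lincRNA gene AC122428.2 (0.62 ± 0.20). Of the fixed list of annotated lncRNAs, 35 were tested, 11 with a positive and 24 with a negative fold change. Airn, the antisense transcript of the imprinted Igf2r locus, had -0.87 ± 0.24, Rian, from the imprinted Dlk1 locus, -0.57 ± 0.25, and Meg3, from the same locus, -0.35 ± 0.44. The nuclear lncRNAs Malat1 (1279 ± 33.7 FPKM in controls and 961 ± 265 in diabetic mice, -0.45 ± 0.22) and Neat1 (-0.39 ± 0.23) did not pass either.

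No lncRNA gene of 1172 tested passed in limma, with 0 adjusted over all genes and 0 adjusted over the list alone, and 97 had an unadjusted p under 0.05, 24 higher and 73 lower. The protein-coding genes gave 0 of 13697 past the threshold and 1223 at an unadjusted p under 0.05. The annotated lncRNA list had a median log2 fold change of -0.35 (camera adjusted p = 0.106), and -0.13 after the GC correction (adjusted p = 0.172). It was called lower without control replicate 3 (adjusted p = 0.0481) and without diabetic replicate 3 (0.0218). These calls are at the preset correlation. With an estimated correlation and all 6 libraries the camera adjusted p of the list was 0.93. Across the 1172 lncRNA genes the median log2 fold change was -0.13, and per library the median deviation was 0.04, 0.17 and 0.03 in controls and 0.09, -0.25 and 0.02 in diabetic mice (exact permutation p = 0.4, two-sided; 0.1 is the smallest p that 3 against 3 allows). The 198 sense-intronic genes had a median of -0.47, with diabetic replicate 2 at -0.75 and the other diabetic libraries at 0.26 and -0.16. Without diabetic replicate 1, 26 lncRNA genes and 288 protein-coding genes passed. After the GC correction the median of the lncRNA genes was -0.05, and 56 of 1170 had an unadjusted p under 0.05, where chance gives 58.5. The fold change of Gm26779 was then -0.67, that of Malat1 -0.18 and that of Rian -0.28.

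No marker of the sensory neuron types passed the test. Calca, which encodes the neuropeptide CGRP, was at 165 ± 17.8 FPKM in controls and 177 ± 19.6 in diabetic ganglia (log2 fold change 0.09 ± 0.14), and Tac1, the substance P precursor, at 26.4 ± 2.94 and 26.7 ± 2.20. The heat-gated channel Trpv1 (0.13 ± 0.13), the cold-gated channel Trpm8 (-0.15 ± 0.15) and Mrgprd of non-peptidergic nociceptors (0.01 ± 0.17) did not pass. Of 13 peptidergic markers 11 had a positive fold change, with Smr2 at -0.93 ± 0.34 and Sstr2 at 0.49 ± 0.22. Of 12 mechanoreceptor and proprioceptor markers 8 were negative, with the transcription factor Etv1 at -0.44 ± 0.15 and the neurotrophin receptor Ntrk3 at -0.31 ± 0.12. In the cold-sensing list, Kcnk4 had 0.37 ± 0.18 and Gpr26 0.23 ± 0.22. Among 20 pan-neuronal markers Elavl4 (37.7% GC) had -0.38 ± 0.13 and Rbfox3 (64.4% GC) 0.37 ± 0.14. In the non-peptidergic list, somatostatin (Sst) was at 33.7 FPKM in diabetic replicate 1 and at 3.41 to 8.59 in the other 5 libraries, and Mrgpra3 had -0.38 ± 0.24. Of 40 ion channel genes 23 were positive, among them Asic2 (0.31 ± 0.11) and Kcnc1 (0.33 ± 0.12).

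Genes of nerve injury, glia and synapses showed the following values. Atf3, a transcription factor induced by axon injury, was at 3.78 ± 1.75 FPKM in controls and 4.63 ± 1.27 in diabetic mice (0.36 ± 0.34), and the injury-induced neuropeptide Gal had 0.35 ± 0.17. Npy, another injury-induced neuropeptide, was at 4.47 FPKM in diabetic replicate 1 and at 0 to 0.966 in the other 5 libraries. Its log2 fold change was 1.86 ± 1.05, and 0.83 without diabetic replicate 1 and 1.06 without control replicate 2. Of 21 synaptic vesicle genes 13 were positive, including Syp (0.43 ± 0.12) and Stx1a (0.69 ± 0.21). Of 18 neurotrophic genes 11 were positive (median 0.04), and Igf1 had -0.44 ± 0.19, and 0.0058 after the GC correction. Of 18 myelin genes 11 were positive (median 0.15). The 2 with the smallest p were lower: Mbp (168 ± 9.73 and 139 ± 6.25 FPKM) had a log2 fold change of -0.27 ± 0.11, and Ugt8a, an enzyme of myelin lipid synthesis, -0.27 ± 0.14. The satellite glia markers Fabp7, Apoe and Cdh19 had -0.17 ± 0.27, 0.32 ± 0.19 and -0.54 ± 0.16. The repair Schwann cell genes Jun and Olig1 had 0.22 ± 0.15 and 0.71 ± 0.50. No member of these lists passed in limma, adjusted over all genes or adjusted over the list alone. By camera the adjusted p was 0.0678 for synaptic vesicle genes, 0.163 for nerve injury genes, 0.709 for myelin genes and for satellite glia, and 0.409 for peptidergic markers. It was 0.184 for mechanoreceptor and proprioceptor markers, 0.186 for repair Schwann cells, 0.463 for ion channels, 0.492 for pan-neuronal, 0.703 for cold-sensing, 0.709 for neurotrophic and 0.791 for non-peptidergic genes.

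No list of immune cells, immune responses or nuclear-encoded metabolism passed. Of 20 interferon response genes 14 were positive (median 0.19, camera adjusted p = 0.0768), with Isg15 at 3.10 ± 0.413 FPKM in controls and 5.26 ± 1.14 in diabetic mice (0.73 ± 0.19) and Bst2 at 0.41 ± 0.16. Of 18 genes of antigen presentation 16 were positive (adjusted p = 0.106), with Tap1 at 0.35 ± 0.18 and B2m at -0.19 ± 0.12. Macrophage genes (adjusted p = 0.409) held Tyrobp at 0.43 ± 0.19 and Mrc1 at -0.33 ± 0.21. The chemokine Cx3cl1 was at 23.1 FPKM in diabetic replicate 1 and at 0.747 to 3.17 in the other 5 libraries, and Ccl5 had 0.73 ± 0.33 (cytokine list, adjusted p = 0.409). For glycolysis 17 of 20 entries were positive (adjusted p = 0.0678), with Aldoa, listed under 2 identifiers, at 0.29 ± 0.14 for the identifier with the smaller p and Pfkm at 0.19 ± 0.10. In the list of polyol, hexosamine and glycation genes Gfpt1 had -0.35 ± 0.16 and Ogt -0.42 ± 0.20, and in oxidative stress defence Gclm had -0.49 ± 0.23 and Nfe2l2 -0.24 ± 0.11, with adjusted p = 0.820 and 0.712. Insulin and IGF signalling (adjusted p = 0.709) included Pik3r1 at -0.21 ± 0.11.

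Transcripts encoded by mitochondrial DNA fell and erythrocyte transcripts rose as lists in the camera test. All 13 mitochondrially encoded genes were lower in diabetic ganglia, with a median log2 fold change of -0.65 (camera adjusted p = 2.75e-05; adjusted p = 0.93 with an estimated correlation). The ATP synthase subunit mt-Atp8 had -1.12 ± 0.40 and the complex I subunit mt-Nd3 -0.91 ± 0.37, and none of the 13 passed alone. Their share of summed FPKM was 5.46%, 4.57% and 4.19% in controls and 4.46%, 2.88% and 2.10% in diabetic replicates 1, 2 and 3 (exact permutation p = 0.2, two-sided), so diabetic replicate 1 lay within the control range. Of 46 nuclear genes of oxidative phosphorylation 30 were positive, with a median of 0.07 (adjusted p = 0.106); Ndufa2 had 0.78 ± 0.26 and Ndufa5 -0.36 ± 0.13. All 6 erythrocyte genes were higher, with a median of 0.54 (camera adjusted p = 0.00433; adjusted p = 0.93 with an estimated correlation), among them the anion exchanger Slc4a1 (0.532 ± 0.127 and 1.22 ± 0.291 FPKM, 1.05 ± 0.29) and the beta globin Hbb-bt (169 ± 39.5 and 268 ± 81.8 FPKM, 0.65 ± 0.25). The median deviation of the erythrocyte list was -0.66, -0.34 and 0.21 in controls and 0.31, -0.18 and 0.64 in diabetic replicates 1, 2 and 3 (exact permutation p = 0.2, two-sided). Diabetic replicate 2 thus lay within the control range. Adjusted over the list alone, 1 erythrocyte gene passed, Slc4a1.

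These were the only calls of camera at its preset correlation among 38 lists with at least 5 tested members, with all 6 libraries and no GC correction; fry called 0, and with the GC correction 6 lists were called. Without control replicates 1, 2 and 3 in turn 5, 5 and 16 lists were called, and without diabetic replicates 1, 2 and 3 there were 2, 5 and 8. Interferon response genes were called higher without control replicate 2, control replicate 3 or diabetic replicate 3. Synaptic vesicle genes were called higher without control replicate 1, control replicate 3 or diabetic replicate 3. Nuclear oxidative phosphorylation genes were called higher without control replicate 1, diabetic replicate 1 or diabetic replicate 3. Nerve injury genes and glycolysis were called higher without control replicate 3 or diabetic replicate 3, and antigen presentation without control replicate 2 or control replicate 3. Macrophage, cytokine and peptidergic lists were called higher without control replicate 3 alone, and the mechanoreceptor and proprioceptor list lower without diabetic replicate 2 alone. These calls are at the preset correlation of 0.01; with an estimated correlation and all 6 libraries, the smallest adjusted p of any list was 0.93, and that setting was not run with a library left out. The 12 lists tested but not described here, among them endothelium, fibroblast, heat shock, circadian clock and cholesterol synthesis, had camera adjusted p between 0.218 and 0.927 with all 6 libraries and no GC correction. Of these, immediate early genes (adjusted p = 0.0448) and pericytes (0.0487) were called higher and heat shock genes (0.0481) lower without control replicate 3, and circadian clock genes higher (0.0333) without diabetic replicate 2. Without diabetic replicate 1, and without both control replicate 2 and diabetic replicate 3, the erythrocyte call was lost (adjusted p = 0.112 and 0.0879, at medians of 0.48 and 0.31 against 0.54), and without control replicate 1 the median of that list was 0.34. The median of the mitochondrially encoded list was -0.34 without diabetic replicate 3, -0.95 without diabetic replicate 1 and -0.27 after the GC correction, and it was called in each (adjusted p = 0.0016, 7.6e-06 and 0.0205). The mitochondrially encoded genes are GC-poor, with a median of 37.1% against 50.4% for all tested genes.

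**Figure D3:**
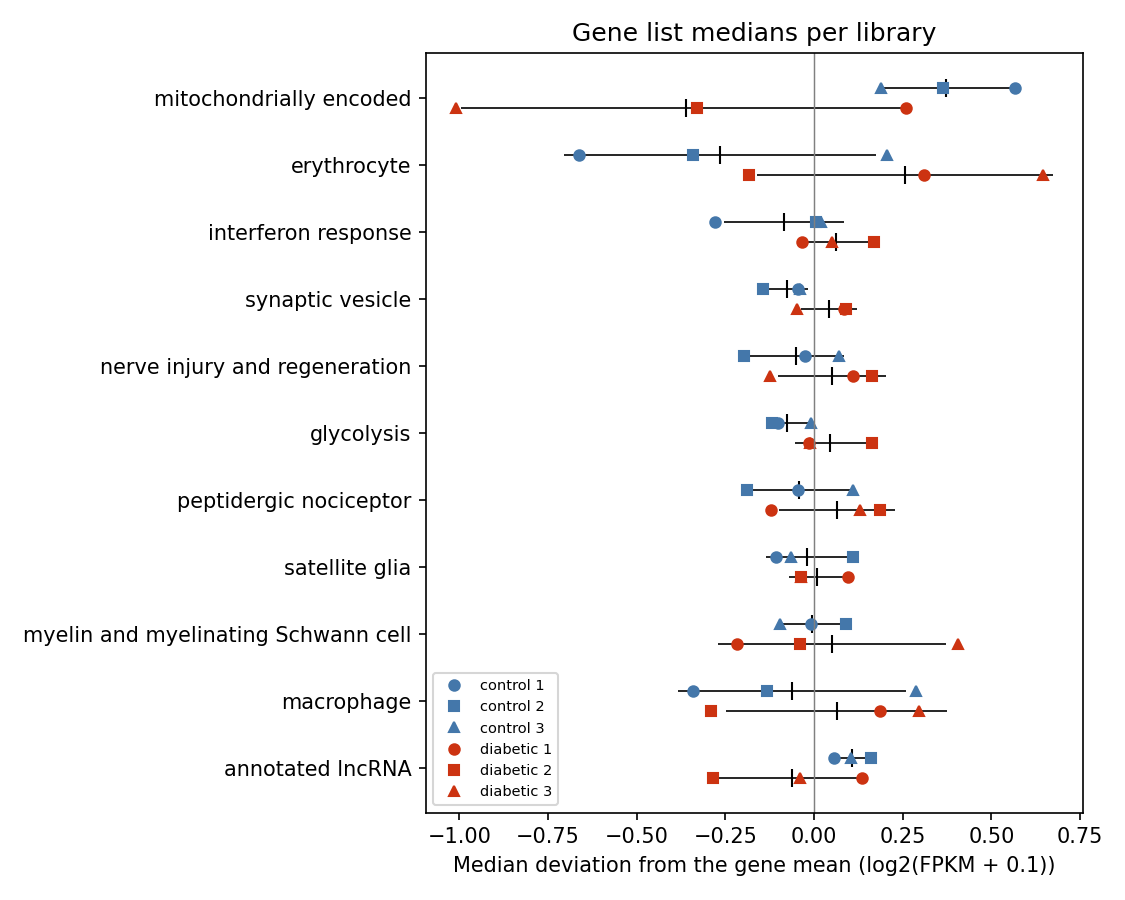
Median deviation from the gene mean (log2 scale) of the members of 11 of the fixed lists, per library; points are libraries, and black ticks with bars are the group mean ± SD. The mitochondrially encoded list reaches -1.01 in diabetic replicate 3 and lies at 0.26 in diabetic replicate 1, inside the control range.

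Some transcripts of other tissues were far higher in 1 library than in the rest. Growth hormone (Gh) was at 2440 FPKM in control replicate 2 and at 6.94 to 68.9 in the other 5 libraries, prolactin (Prl) at 364 against at most 4.83, and Pomc at 247 against at most 5.73. The pituitary list thus had a median log2 fold change of -1.63 (camera adjusted p = 0.409), with Lhb at -2.53 ± 1.91 and Pou1f1 at -1.67 ± 1.52. Without control replicate 2 the list turned and was called higher (adjusted p = 0.0239), as it was without control replicate 2 and diabetic replicate 3 together (0.0188). It was called lower without control replicate 1 (0.0228) and without control replicate 3 (0.0225). Besides control replicate 2, Gh was at 68.9 and 37.1 FPKM in diabetic replicates 1 and 3. In control replicates 1 and 3 and diabetic replicate 2 it was at 6.94 to 10.7. Prl was at 4.83 and 2.79 in diabetic replicates 1 and 3, against 0.635 to 0.872 in those libraries. Pomc did not follow this order, with 5.50 in control replicate 3 and 1.87 in diabetic replicate 3. Transthyretin (Ttr), an abundant choroid plexus transcript, was at 290 FPKM in diabetic replicate 1 and at 0.491 to 2.39 in the others. Sst, Npy and Cx3cl1 were also highest in that library, and whether they share a source with Ttr was not tested. The central nervous system list, which holds Ttr, had its highest median deviation in diabetic replicate 1 (0.50). Its adjusted p was 0.217, and it was called higher without control replicate 3 (0.0448) or diabetic replicate 2 (0.0109), and Slc17a7 had 0.44 ± 0.19. The calls of this list and of the pituitary list are at the preset correlation. With an estimated correlation and all 6 libraries, the camera adjusted p of each was 0.93.

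The third comparison, of single isoforms, gave calls. The isoform Sqstm1-205 of the autophagy receptor gene Sqstm1 was listed at 0 in all controls and rose to 102 ± 18.7 FPKM in diabetic ganglia, while Sqstm1-201 fell from 42.0 ± 3.58 to 10.2 ± 1.85 FPKM. Lsm4-205, of a U6 small nuclear RNA binding protein, and Klhdc4-205 were also listed at 0 in all controls and rose to 17.7 ± 6.95 and 3.16 ± 1.12 FPKM. Usp35-202, of a deubiquitinase, rose from 0.00187 ± 0.00223 to 15.6 ± 3.57 FPKM, and the retained-intron isoform Slc25a22-212 from 0.163 ± 0.0643 to 7.11 ± 0.872 FPKM. The gene-level value of Slc25a22 fell from 6.44 ± 0.375 to 3.71 ± 0.460 FPKM. In diabetic ganglia it lay below that of this isoform alone, so gene and isoform values disagree for Slc25a22. Baz2b-201 fell from 5.55 ± 1.52 FPKM to 0 in all diabetic libraries, Ppme1-204, of the protein phosphatase methylesterase gene, from 14.5 ± 0.172 to 0.312 ± 0.278, and Zbtb7b-201 from 6.23 ± 0.719 to 0.508 ± 0.192.

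Of 43425 transcripts tested, 14 passed in limma, 10 higher and 4 lower, from 13 genes, and the groups did not overlap for any of them. At an unadjusted p under 0.05 there were 2426, where chance gives 2171.25. None of the 14 belonged to an lncRNA gene. As a share of the summed FPKM of the gene's listed isoforms, Sqstm1-205 went from 0% to 63.4% ± 2.21 (SD, n = 3), Zbtb7b-201 from 77.5% ± 4.92 to 4.85% ± 0.337, and Ccm2-201 from 15.3% ± 2.97 to 82.4% ± 3.26. None of the 13 genes passed as a whole. The log2 fold change of the gene was -0.41 ± 0.13 for Sqstm1, 0.22 ± 0.23 for Zbtb7b and 0.08 ± 0.12 for Ccm2. For Sqstm1 the gene and isoform values disagree as well. The summed FPKM of its listed isoforms lay above every control in diabetic replicates 2 and 3. In diabetic replicate 1 it lay below every control. An exact 0 for an isoform can be a failed estimate, and isoforms of 1 gene share most of their sequence. The sources used here do not say whether all 6 libraries were quantified in 1 run, so a difference in quantification between the groups would enter these shares. Without control replicate 2 and diabetic replicate 3 together, 0 transcripts passed, and without diabetic replicate 1, 47 did, 10 of them among the 14. Of the 14, 6, 4 and 4 passed without control replicates 1, 2 and 3, and 5 and 6 without diabetic replicates 2 and 3.

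**Figure D4:**
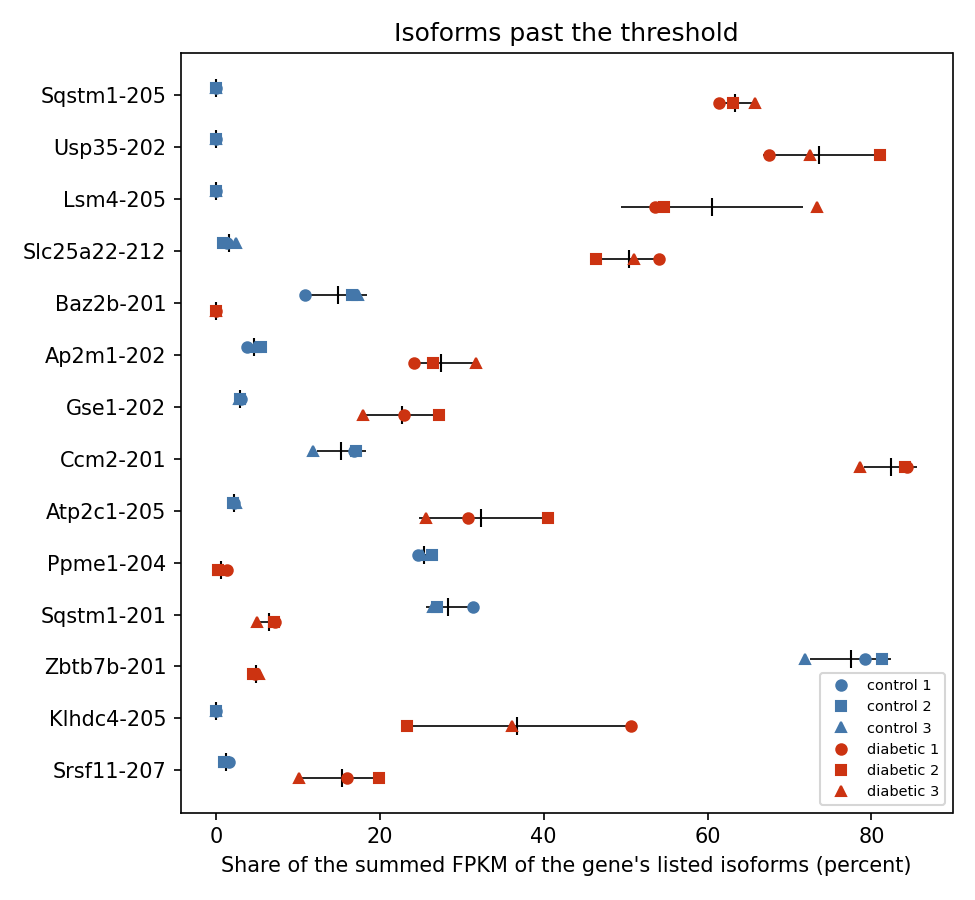
Share of each of the 14 called isoforms in the summed FPKM of its gene's listed isoforms, in percent, per library; points are libraries, and black ticks with bars are the group mean ± SD. Sqstm1-205 lies at 0% in all 3 controls and at 61.4% to 65.7% in the diabetic libraries.

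The last comparison set lncRNAs beside their nearest protein-coding genes. Gm26779 (-1.06 ± 0.22) and its nearest coding gene, Gm15446 (-0.74), 32263 bp away, had the same sign, whereas Gm13054 lay 245 bp from Clcn6 (0.16) and Gm40117 (0.88 ± 0.24) overlapped Cttnbp2nl (-0.18). As no lncRNA passed, the 100 with the smallest p were taken. Of the 90 with a coding gene within 100 kb, 63 (70.0%) had a fold change of the same sign as that gene, against a mean of 60.2% over 1000 draws of lncRNAs matched in expression (two-sided permutation p = 0.0519). This did not pass; within 500 kb the share was 71.0% (permutation p = 0.028). Genes are not independent replicates, and this share is a description of these libraries. The draws were not matched in the size or direction of the fold change, so the choice of lncRNAs by small p could itself raise the share.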

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

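No read depth is known, so its limit on these values cannot be given, and 3 libraries per group limit every test. The alternatives with a GC correction, and those that leave out control replicate 2 and diabetic replicate 3 together, were chosen after the data were seen. Where a value moved, the cause was not tested, with 2 exceptions. Leaving out libraries lowers their number, and the calls without diabetic replicate 1 were tested against the GC trend: of the 313 with a GC value, 0.639% kept their call after the GC correction. Many of these calls lay just under the threshold before it (adjusted p = 0.0482 for Pigc and Rcbtb1). A small shift of any kind would lose them, so the lost calls alone do not show the trend as their cause.

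The count of genes past the threshold stayed at 0 with the replicate block, other pseudocounts, filters, scalings and variance models, with adjusted p under 0.1 and with the GC correction. It ranged from 0 to 314 when each library was left out (lncRNA genes 0 to 26, protein-coding genes 0 to 288), the high values being those without diabetic replicate 1. With the GC correction and without diabetic replicate 1 it was 2, both protein-coding (2), Zfp281 and Hist2h2aa1, named after their values were seen. At unadjusted p under 0.05 and 1.5-fold there were 374 genes, 80 lncRNA and 294 protein-coding, and this count ranged from 168 to 1382 when each library was left out. It was 156 with a pseudocount of 1, 767 with array quality weights, 126 with the GC correction, 139 with the GC correction and replicate block, and 148 without control 2 and diabetic 3. The share of higher genes among these 374 was 43.6%. It was 65.9% without control replicate 2, 70.0% without diabetic replicate 2, 54.8% without diabetic replicate 3 and 31.4% without diabetic replicate 1. It was 57.7% with a pseudocount of 1, 55.6% with the GC correction, 57.6% with the GC correction and replicate block, and 67.6% without control 2 and diabetic 3, so its majority turned. It was 49.5% with quantile scaling and 27.8% with array weights.

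The count of transcripts, 14, ranged from 11 to 47 when each library was left out, with 4 to 10 of the 14 among them, and was 28 at adjusted p under 0.1, 2090 at unadjusted p under 0.05 and 1.5-fold, and 0 without control 2 and diabetic 3. With the replicate block 3 passed, Sqstm1-205, Usp35-202 and Lsm4-205, all shared with the 14. The block left the gene count at 0 and kept both list calls. Same-numbered libraries correlated at -0.21, -0.19 and 0.13 in their deviations from the group means, and 2 of 6 libraries correlated best with their own number. These values give no sign that the numbers pair the libraries, but with 3 libraries per group they cannot exclude a pairing.

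The 2 lists called became 0 with an estimated correlation (adjusted p = 0.93 at medians of -0.65 and 0.54) and 0 with fry (adjusted p = 0.916), 6 with the GC correction and 4 without control 2 and diabetic 3, and ranged from 2 to 16 when each library was left out. The pituitary list, lower and not called in the main test, was called higher without control replicate 2 (adjusted p = 0.0239) and without control 2 and diabetic 3 (0.0188). The median of the erythrocyte list was 0.31 without control 2 and diabetic 3 and ranged from 0.34 to 0.80 over the libraries left out. The mitochondrially encoded list was called in all of these but the estimated correlation and fry, while its median of -0.65 ranged from -0.95 to -0.34 over the libraries left out, and was -0.27 with the GC correction and -0.34 without control 2 and diabetic 3. For lncRNA neighbours the share was 71.0% within 500 kb (mean of the matched draws 60.8%) and 66.7% with the GC correction (53.2%; permutation p = 0.009), both past the threshold, and 68.6% within 50 kb (60.01%), not past it. In the main test it was 70.0% against 60.2%.

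Of the 77 genes that the naming rule takes, 17 changed sign in at least 1 alternative, all with fold changes that did not pass. Over the libraries left out, the log2 fold changes were Fabp7 -0.44 to 0.060, Lhb -3.91 to 0.071, Pou1f1 -2.67 to 0.31, Tac1 -0.072 to 0.088, Mrgprd -0.18 to 0.14, Atf3 -0.0097 to 0.69, Gpr26 -0.035 to 0.42 and Meg3 -0.65 to 0.24. With the GC correction they were Elavl4 0.0698, Rbfox3 -0.024, Igf1 0.0058, Ugt8a 0.088, B2m 0.13 and Fabp7 0.14. With the GC correction and replicate block they were Elavl4 0.0698, Rbfox3 -0.024, Igf1 0.0058, Ugt8a 0.088, B2m 0.13 and Fabp7 0.14. With the GC correction and without diabetic replicate 1 they were Elavl4 0.19, Rbfox3 -0.059, Igf1 0.064, Cdh19 0.0092, Apoe -0.051, Ugt8a 0.26, B2m 0.26, Slc17a7 -0.010 and Fabp7 0.19. Without control 2 and diabetic 3 they were Pou1f1 0.39, Calca -0.011, Tac1 -0.026 and Fabp7 0.15. With quantile scaling they were Tac1 -0.028 and Mrgprd -0.046.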

Other observations

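Tests of the GC correction and of control replicate 2, those on whether the diabetic animals acted alike, and the counts of other splits for genes, lncRNA genes and protein-coding genes were chosen after the results were seen. The bound for the diabetic animals acting alike was changed after its values were known, from diabetic replicate 1 alone to a count over the 3 diabetic libraries; by the first bound, the values of diabetic replicate 1 would count against that explanation.

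After the GC correction, 6 of 38 lists passed in the camera test. Interferon response genes were higher, with a median log2 fold change of 0.26 (adjusted p = 0.000226; unadjusted p = 0.172 with an estimated correlation); Isg15, an interferon-induced ubiquitin-like protein, had a log2 fold change of 0.73 before the correction and 0.67 after it and did not pass in either. Nerve injury genes (median 0.18, adjusted p = 0.0205) and synaptic vesicle genes (0.12, 0.0197) were higher, as were nuclear oxidative phosphorylation genes (0.06, 0.042) and erythrocyte genes (0.42, 0.00299). Mitochondrially encoded genes stayed lower (-0.27, 0.0205). None of these lists was called with an estimated correlation, where unadjusted p lay between 0.135 and 0.469. No single gene passed in limma after the correction (0 of 14850), and 548 had an unadjusted p under 0.05, fewer than the 742.5 that chance gives.

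The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real count of genes was 0, and so were those of lncRNA genes and of protein-coding genes. All 10 splits give at least 0, so these 3 counts decide nothing; the highest other value was 1 for each. For genes at an unadjusted p under 0.05, the real count was 1320 and the highest other was 1547. With a change of 1.5-fold as well, the real count was 374, the highest other was 509, and 4 of the 10 splits gave as many. For transcripts the real count was 14, the highest other 17, and 2 of 10 gave as many. For lists, the real count was 2, the highest other 23, and 10 of 10 gave as many. The 9 other splits called 5 to 23 lists, so list calls at the preset correlation of 0.01 also arise between sets of libraries that mix the groups.

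Fold changes followed GC content (rho = 0.69). A neuronal and synaptic gene programme, as the source of the trend, is argued against by rho = 0.70 over 67 genes of the macrophage, endothelium, pericyte and fibroblast lists (bootstrap 95% interval 0.53 to 0.83). GC-dependent recovery that differs between libraries may contribute: among 1182 genes with protein-coding isoforms at least 5 points apart in GC, the isoform with more GC had the higher fold change in 72.1% (exact 95% binomial interval 69.4% to 74.6%). Both intervals treat genes of the same 6 libraries as independent and leave out the spread between libraries. Diabetes acting alike on every treated animal cannot be told apart from such recovery. The slopes of 2 of the 3 diabetic libraries were 0.31 and 0.55 from the control mean, and that of diabetic replicate 1 was 0.08 from it. All 3 lay above every control slope (-0.07, 0.15 and 0.40 against -0.18, -0.15 and -0.14). The bound here was a distance from the control mean, while that for the mitochondrial share below was the control range. Without diabetic replicate 1, 314 genes were called, with a median GC content of 59.2% in the higher and 40.2% in the lower ones. Of the 313 with a GC value, 0.639% kept the call after the GC correction in the same 5 libraries. Many calls lay just under the threshold before it (adjusted p = 0.0482 for Pigc and Rcbtb1), so their loss alone does not show the trend as the cause.

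Mitochondrially encoded transcripts were lower by a median of -0.65 (SE 0.074 over 13 members; -0.34 without diabetic replicate 3), and by -0.27 (SE 0.067) after the GC correction, a value between the bounds set for the trend as the whole cause and for it as no cause. It therefore cannot be told apart whether the GC trend is the source of all of it. Both SEs are those of the mean fold change, not of the median, over the 13 members, which vary together (estimated correlation 0.70). They do not measure the spread between libraries. Diabetes acting alike on every treated animal also stays open, as 2 of 3 diabetic libraries lay below the control range. Diabetic replicate 3, the lowest in mitochondrially encoded share, had 3.37% of summed FPKM in Gm26917 and Gm42418, 2 genes at rRNA repeats chosen after their values were seen, against 1.39% to 1.89% in the other 5 libraries (exact permutation p = 0.4, two-sided). In diabetic replicate 2 the median deviation of retained-intron transcripts was -0.51, against 0.05 to 0.23 in the other 5. The tables hold no measure of RNA integrity, and no prediction about RNA quality was set against these values.

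Of the 12 pituitary transcripts in the gene table, 91.7% were highest in control replicate 2, where Gh was 35.4 times and Lhb 199 times the highest other library. The exception was Chga, which sensory neurons express too (58.3 FPKM there and 63.8 in diabetic replicate 2). Pituitary tissue in the dissected sample, from the gland next to the ganglion, is a candidate explanation. The series gives no group that would offer a biological one, and none was tested.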
